A study of Mus musculus with 3 samples.

How the data were processed

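Small RNA libraries were made from exosomes of C57BL/6 wild-type bone-marrow-derived macrophages of mice, 3 libraries in 1 group. Per the labels' protocols, conditioned medium was cleared by centrifugation and filtration and pelleted by ultracentrifugation, RNA was extracted with TRIzol, adapters were ligated to the 3′ and then the 5′ ends, and libraries were amplified by PCR, size-selected on a gel (NEBNext small RNA kit) and sequenced as single-end reads of 50 bases on an Illumina HiSeq. The kit adds no molecular identifiers that the labels mention, so counts are of PCR products, and ligation and PCR can favour some sequences over others. Bcl2fastq, BWA and the mouse build mm10 are named, without versions, in the submitters' processing notes. Adapter trimming, mismatch limits, the miRNA annotation release and the treatment of reads that match several miRNAs were not given in the sources used here.

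Each library has a table of 1915 mature mouse miRNAs. The authors deposited a whole-number count per miRNA, which is the unit of all tests here, and beside it a normalized value, RPM. As worked out from the deposited columns, the RPM of a miRNA is its count per 1000000 of a denominator of 14047692, 13995845 and 14002577 in libraries 1, 2 and 3. The miRNA counts make up 21.4%, 17.8% and 22.9% of these denominators, and what else they contain is not given in the sources used here. Because of this, counts were scaled to the miRNA total of each library (counts per 1000000 miRNA counts, CPM), and the authors' RPM served as an alternative chosen after seeing the data. In 3 sets of miRNAs with a summed count of at least 30 the counts were identical in all libraries, namely miR-486a-5p with miR-486b-5p, let-7a-1-3p with let-7c-2-3p, and miR-199a-3p with miR-199b-3p. Such reads therefore appear under both names, and near-identical family members such as those of let-7, miR-23 and miR-146 can share reads through sequencing errors.

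The libraries held 3008995, 2489984 and 3208617 miRNA counts. A miRNA with 0 counts could have up to 0.997, 1.20 and 0.935 CPM in libraries 1, 2 and 3 (3 counts). Shares of counts in single libraries carry 95% Wilson intervals, which, like the floors and the intervals of arm ratios, cover counting error only and not the spread between libraries. Groups were taken from the sample labels, and with 1 group no comparison between conditions was possible.

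Detected miRNAs, shares and list sums are given as mean and SD over the 3 libraries. Agreement was measured by Pearson and Spearman correlation of log2(CPM + 1) over miRNAs with a mean CPM of at least 1, and by edgeR's common dispersion. A chi-square test compared the 3 counts of each miRNA with the library totals, with Benjamini-Hochberg adjustment over miRNAs with a summed count of at least 30. It compares these libraries and not conditions. On simulated Poisson counts for its 353 miRNAs, with 200 changed 1.5-fold in 1 library, it recovered 74.0% and called 3 of 153 unchanged miRNAs. Such counts hold counting error only, which is what the test assumes. The few false calls therefore do not carry over to libraries with further technical spread.

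The arm test used edgeR's quasi-likelihood test on the 5p and 3p counts of each precursor with both arms in the table, with library and arm as terms, library sizes equal to the miRNA totals and a summed count of at least 60. Arms were matched by miRNA name, which gave 749 such precursors, of which 157 passed that filter. Gene copies whose arms share a name count as 1. Hairpins with a copy number in the name of 1 arm only had no match. Examples of such arms are miR-24-2-5p, miR-125b-2-3p, let-7a-1-3p and let-7c-2-3p. The arm test and its shares therefore leave out miR-24, miR-125b, let-7a and let-7c, among others. MiR-486a and miR-486b, and miR-199a and miR-199b, were tested separately although their main arms carry the same counts. On simulated data for 152 precursors the arm test recovered 0% of 2-fold, 10% of 4-fold and 75% of 16-fold differences and called 1 of 92 unchanged precursors. An arm at 0 counts is given by a bound against 3 counts per library, since a fitted ratio then depends on edgeR's prior count.

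Before the data were examined, 29 lists of miRNAs (families, genomic clusters, cell types, macrophage pathways, vesicle sorting) were fixed. Of their 181 distinct members 174 were matched to a name in the tables. The placement of a list is its median percentile among detected miRNAs, set against 10000 random lists of the same size from all miRNAs in the table. The chi-square counts of 26 of the 27 lists with a tested member were the same when adjusted over the list alone. The exception was Dlk1-Dio3, with 5 of 6 members over all miRNAs and 4 of 6 adjusted over the list alone. The named miRNAs were fixed by rule before the data were examined. They are the 20 with the highest mean CPM, the 3 highest members of each list and all members of lists of 5 or fewer, the 5 precursors with the largest and the 5 with the smallest arm ratio among those called with at least 60 counts in every library, the 5 most and 3 least variable miRNAs with a mean of at least 100 CPM, and miR-155-5p and miR-146a-5p. Other list members named in the text, and hairpins that switched arms, were chosen after their values were seen.

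Positions come from the GENCODE annotation of GRCm38, the build that mm10 denotes, by matching the mature sequence to the annotated precursor of the same name. Mature sequences of the 98 miRNAs with a mean of at least 300 CPM were entered by hand from general knowledge of miRNA sequences and kept only where they occurred exactly in the annotated precursor on the named arm, which held for all 98. GC content was taken from these sequences. Permutation tests of correlations and of clusters were two-sided with 100000 permutations, and bootstrap intervals used 2000 draws of miRNAs. Random regrouping of miRNAs into clusters used 10000 shuffles and a one-sided p for narrower gaps. These p-values and intervals are over miRNAs or clusters, which are not independent replicates.

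Alternatives included leaving out each library, TMM and DESeq2 scaling, other count minimums and pseudocounts, thinning to the smallest library, DESeq2 and limma for the arm test, and a model without the library term. Software was R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The reads themselves, parent cells, other small RNA classes and sequence variants of miRNAs were not analysed here.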

Results

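MicroRNAs (miRNAs) were sequenced in exosomes, small membrane vesicles released by cells, that wild-type C57BL/6 mouse bone-marrow-derived macrophages shed into their culture medium. Marrow cells from the leg bones were grown with M-CSF, the growth factor that drives macrophage formation, for 24 h and then in medium with exosome-depleted serum. Vesicles were collected by ultracentrifugation after 72 h. The stated purpose was to profile the miRNAs that these exosomes carry. There was 1 group with 3 libraries, replicates 1, 2 and 3, called libraries 1 to 3 here. Their titles carry an abbreviation, CHMP, that the labels do not explain. The labels do not say whether the libraries came from separate cultures or animals, so the SDs and the p-values of the arm test measure only the spread between these libraries, which may be technical. The libraries held 3008995, 2489984 and 3208617 counts assigned to mature miRNAs. At these depths 3 counts, the most that a count of 0 allows, corresponded to 0.997, 1.20 and 0.935 counts per 1000000 miRNA counts (CPM). Wilson and counting intervals and floors cover counting error only. With no library of the parent cells, the levels are those of the exosome pellet, including any RNA that pelleted with the vesicles, and carry no comparison with the cells.

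The most abundant miRNA was miR-21a-5p, which is induced in macrophages by inflammatory signals. It took 20.1% ± 14.4 of miRNA counts (SD, n = 3), with 37316, 305278 and 261488 CPM in libraries 1, 2 and 3. Next came miR-99a-5p at 9.71% ± 6.53, let-7i-5p at 7.79% ± 2.43, let-7f-5p at 4.79% ± 3.75 and miR-146b-5p at 4.35% ± 3.74 (SD, n = 3 each). They were followed by miR-7a-5p at 3.97% ± 2.71, miR-27b-3p at 3.74% ± 1.99 and miR-146a-5p, an NF-κB-induced brake on Toll-like receptor signalling, at 3.50% ± 0.157 (SD, n = 3 each). Ranks 9 to 20 were taken, in this order, by miR-24-3p, miR-30d-5p, let-7g-5p, miR-92a-3p, miR-140-3p, miR-221-3p, miR-378a-3p, miR-27a-3p, miR-30a-5p, miR-23a-3p, miR-25-3p and let-7c-5p, from 3.03% down to 1.36%. Library 1 decided several of these means. Without it miR-99a-5p averaged 5.97%, and the means of miR-24-3p, miR-30d-5p, miR-92a-3p, miR-140-3p, miR-378a-3p, miR-23a-3p and miR-25-3p were also lower by more than 1.5 times. MiR-378a-3p went from 1.77% to 0.550% and miR-23a-3p from 1.47% to 0.398%. Without library 3, miR-146b-5p averaged 24380 CPM in place of 43483. Leaving out library 1 kept 16 of the 20 names, and miR-5099, let-7a-5p, miR-10a-5p and miR-183-5p replaced the others.

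In the GRCm38 (mm10) annotation, the miR-21a-5p sequence lies on chromosome 11 at 86584120 to 86584141, minus strand, in a precursor that overlaps an exon of the protein-coding gene Vmp1. The miR-99a-5p sequence lies on chromosome 16 at 77598940 to 77598961, plus strand, within an intron of the noncoding host gene Mir99ahg. For let-7i-5p the position is chromosome 10 at 122985698 to 122985719, minus strand, in an exon of the transcribed pseudogene D630033A02Rik. The let-7f-5p sequence is encoded in 2 precursors, on chromosome 13 at 48537889 to 48537910 in an exon of the noncoding RNA 6720427I07Rik and on chromosome X at 151912353 to 151912374 in an intron of Huwe1, so its counts cannot be split between them. The miR-146b-5p sequence lies on chromosome 19 at 46342790 to 46342811, plus strand, in an intron of Mfsd13a, and miR-146a-5p on chromosome 11 at 43374435 to 43374456, minus strand, with no annotated host gene on that strand.

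**Figure D1:**
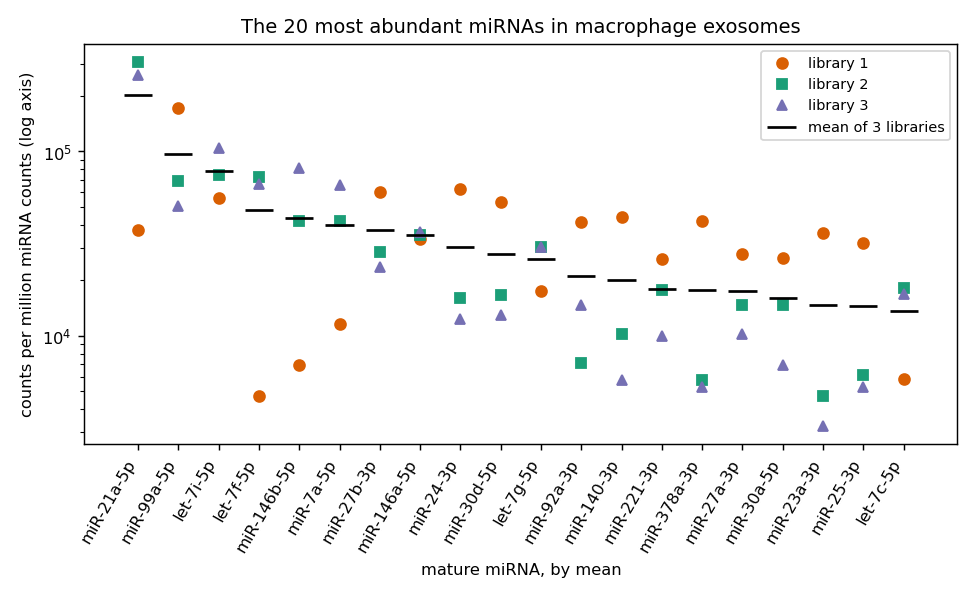
Counts per 1000000 miRNA counts (CPM, log axis) of the 20 miRNAs with the highest mean, in libraries 1 to 3 (points) with the mean of the 3 libraries (black bars). The most abundant, miR-21a-5p, stood at 37316 CPM in library 1 and at 305278 and 261488 in libraries 2 and 3, while miR-146a-5p lay between 33401 and 36543 in all 3.

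A small set of miRNAs made up most of the profile. The top miRNA of each library was miR-99a-5p in library 1, with 17.2% of counts (Wilson 95% interval 17.1 to 17.2), and miR-21a-5p in libraries 2 and 3, with 30.5% (30.5 to 30.6) and 26.1% (26.1 to 26.2). The 10 most abundant miRNAs of a library held 68.7% ± 7.22 of its counts and the 20 most abundant 84.1% ± 2.46 (SD, n = 3 each). Between 26 and 35 miRNAs sufficed for 90% of counts. Of 1915 mature miRNAs listed, 886 had a count in at least 1 library, 505 had a count in all 3, and 273 had at least 10 counts in all 3. The mean reached 100 CPM for 134 miRNAs.

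The let-7 family, whose members repress growth and cell-cycle genes, was the most abundant of the families and clusters examined in libraries 2 and 3 and by the mean. In library 1 it stood below the miR-232724 clusters and the clusters with miR-99a-5p, at 18.7% and 18.6%. Its 9 members together took 18.2% ± 8.20 of counts (SD, n = 3), at 8.76%, 21.8% and 23.9% in libraries 1, 2 and 3, and all 9 had at least 10 counts in every library. The clusters that join miR-99 or miR-100, let-7 and miR-125 genes took 11.9% ± 5.89, mostly as miR-99a-5p, and shared let-7c-5p and let-7e-5p with the let-7 family. The let-7c-5p sequence is also encoded on chromosome 15, next to let-7b, so its counts cannot be credited to these clusters alone. The miR-232724 clusters, led by miR-27b-3p and miR-24-3p, took 10.1% ± 7.54, and 5.75% without library 1. The miR-30 family took 4.76% ± 3.22, led by miR-30d-5p and miR-30a-5p, and 2.94% without library 1. The miR-17~92 cluster, which promotes proliferation, took 3.49% ± 2.54, and 2.02% without library 1. By the mean miR-92a-3p stood above miR-20a-5p and miR-17-5p, but in library 2 miR-20a-5p was higher, at 7258 against 7098 CPM. The sequences of miR-92a-3p and miR-19b-3p are also encoded on chromosome X, so their counts cannot be credited to this cluster alone. The miR-106b~25 cluster took 1.70% ± 1.74, and 0.695% without library 1. The pair of miR-221-3p and miR-222-3p took 2.33% ± 0.781, miR-26 0.636% ± 0.376, miR-15/16 0.387% ± 0.0673, miR-29 0.287% ± 0.0936 and miR-181 0.140% ± 0.0751 (SD, n = 3 for each).

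Library 1 held less of the let-7 and miR-26 families and more of several clusters than either other library. All 9 let-7 members were lower in library 1 than in libraries 2 and 3, from let-7i-5p (55602, 74235 and 103787 CPM in libraries 1 to 3) to let-7e-5p (14.3, 826 and 907 CPM). Both miR-26 members were lower there as well, miR-26a-5p at 1137, 5702 and 6410 CPM and miR-26b-5p at 888, 3027 and 1912 CPM. The summed counts of miR-232724 stood at 18.7%, 6.50% and 4.99%, those of miR-17~92 at 6.41%, 2.03% and 2.01%, those of miR-106b~25 at 3.71%, 0.791% and 0.599%, and those of miR-30 at 8.40%, 3.58% and 2.29% in libraries 1, 2 and 3. Members did not all move with these sums: miR-30c-5p (438, 1899 and 1235 CPM) and miR-30b-5p (260, 747 and 1051 CPM) were lower in library 1 than in both others, as was miR-19b-3p of miR-17~92 (839, 2391 and 1162 CPM). MiR-19a-3p of that cluster (307, 479 and 204 CPM) was lower than in library 2, as was miR-23b-3p (576, 1072 and 536 CPM). Every tested member of these families differed among the 3 libraries by more than counting error in the chi-square test, as did 90.1% of all miRNAs tested, with the same counts adjusted over the list alone (9 of 9 for let-7, 6 of 6 for miR-17~92, 5 of 5 for miR-232724 and for miR-30, 3 of 3 for miR-106b~25, 2 of 2 for miR-26). Scaling by TMM factors moved every log2 ratio of library 1 to library 2 by -0.61 and of library 1 to library 3 by -0.86. The directions of the 6 families' sums named here stayed the same, but those of miR-15/16 turned against both libraries, that of the miR-221-3p and miR-222-3p pair against library 2 and that of miR-29 against library 3. For miR-181 the log2 ratio of library 1 to library 2 went from 0.62 to 0.0075 with TMM factors and to -0.030 with DESeq2 size factors.

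MiRNAs known from macrophages and other myeloid cells took 30.4% ± 15.4 of counts (SD, n = 3), 12.5%, 39.5% and 39.0% by library, mostly as miR-21a-5p, miR-146b-5p and miR-146a-5p. Of the 10 list members in the table, 9 had at least 10 counts in every library. The haematopoietic miR-142a-3p was at 42.9, 1364 and 819 CPM, so that its mean of 742 CPM was 431 without library 2. MiR-223-3p, which is highest in neutrophils, was far lower at 35.6, 52.6 and 33.0 CPM, and miR-511-3p, encoded in the mannose receptor gene Mrc1, had 10, 2 and 0 counts. MiRNAs induced through Toll-like receptors took 25.6% ± 13.95, of which miR-21a-5p was again the main part. The inflammatory miR-155-5p in that list was at 74.8, 2388 and 829 CPM, a mean of 1097 ± 1180 CPM (SD, n = 3) that was 452 without library 2. Its sequence lies on chromosome 16 at 84714143 to 84714165, plus strand, in an exon of Mir155hg. Of the same list miR-132-3p was at 166, 91.97 and 119 CPM, and miR-147-3p had 1 count in each library.

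The list of miRNAs associated with IL-4-activated macrophages took 6.72% ± 1.32 (SD, n = 3). By the mean it was led by miR-146a-5p and by miR-378a-3p, which rises in macrophages given IL-4. MiR-378a-3p was at 42113, 5710 and 5288 CPM in libraries 1, 2 and 3, and let-7c-5p of the same list at 5819, 18255 and 16847 CPM. The second place of miR-378a-3p thus came from library 1, without which it averaged 5499 CPM against 17551 for let-7c-5p. MiR-124-3p of the list had no counts. A list of miRNAs studied in bone formation and resorption took 22.98% ± 13.7, most of it miR-21a-5p and the next largest part miR-27a-3p at 1.76% ± 0.922 (SD, n = 3 each). Every tested member of the myeloid (9 of 9), Toll-like receptor (9 of 9), IL-4 (5 of 5) and bone (12 of 12) lists differed among the libraries by more than counting error, as most tested miRNAs did (90.1%), with the same counts adjusted over the list alone. These lists overlap, and miR-21a-5p counts in 3 of them.

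The lists of other cell types took small shares, but so did some members of the myeloid list. MiR-142a-3p, miR-142a-5p, miR-342-3p and miR-223-3p averaged 742, 500, 107 and 40.4 CPM, while miR-22-3p and miR-378a-3p averaged 4579 and 17704. The contrast with the myeloid list thus rests on its few abundant members. In library 1 miR-142a-3p, at 42.9 CPM, stood below miR-199a-3p of the stromal list, and in libraries 2 and 3 above it. The erythroid list, with miR-451a and the miR-486 pair, took 0.00674% ± 0.00674, the stromal list 0.0269% ± 0.00550, the epithelial list 0.0311% ± 0.0190, the endothelial list 0.00319% ± 0.00110 and the lymphoid list 0.142% ± 0.0748 of counts (SD, n = 3 each). The last was almost all miR-181a-5p and miR-181b-5p, which also count in the miR-181 family. Of the other lymphoid members, miR-150-5p, miR-31-5p, miR-138-5p and miR-205-5p averaged 0.104, 0.379, 1.23 and 36.3 CPM. In the stromal list the highest were miR-199a-3p, at 223, 125.3 and 114 CPM, miR-10b-5p and miR-143-3p. In the epithelial list they were miR-200b-3p, miR-200c-3p and miR-205-5p, the last at 17.6, 87.6 and 3.74 CPM. The neuron list took 0.199% ± 0.152, nearly all miR-128-3p, which is not restricted to neurons. Both miR-126a arms, known from endothelium, were low, at a mean of 29.7 ± 12.2 CPM for miR-126a-3p and 2.23 ± 1.85 CPM for miR-126a-5p. The 23 miRNAs of the imprinted Dlk1-Dio3 region together took 0.00921% ± 0.00366, led by miR-369-3p and miR-127-3p. The muscle list summed to 5.10 ± 0.998 CPM and the stem cell list to 0.824 ± 0.447 CPM, all of it miR-294-3p, and the 16 miRNAs of the Sfmbt2 cluster had no counts in any library. The miR-486 pair has identical counts, and with these counted once the erythroid list took 0.00447% ± 0.00401 (SD, n = 3). Without library 1 the list took 0.00288%, or 0.00218% with the pair counted once, miR-126a-5p averaged 1.18 CPM, and the neuron list took 0.112%.

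The hepatocyte miRNA miR-122-5p had the highest mean of the liver list, which rested on library 3. MiR-122-5p was at 322, 548 and 1500 CPM in libraries 1, 2 and 3, and its mean of 790 CPM fell to 435 without library 3. By the mean the other liver-list members were lower, with miR-192-5p at 672 ± 342 CPM and miR-194-5p at 75.5 ± 42.8 CPM. In library 1, however, miR-192-5p was above miR-122-5p, at 1067 CPM, and without library 3 it averaged 774 CPM. The list as a whole took 0.155% ± 0.0446 (SD, n = 3 each). The list of miRNAs abundant in serum took 2.61% ± 1.83, or 1.63% without library 1. Most of it was miR-92a-3p, which is also in the miR-17~92 list. MiRNAs reported as sorted into vesicles took 0.175% ± 0.0714, led by miR-320-3p, and miRNAs reported as retained in cells took 1.26% ± 0.249 (SD, n = 3 each). The latter were led, by the mean, by miR-17-5p, miR-29a-3p and let-7d-5p. This order came from library 1, without which let-7d-5p averaged 3129 CPM, miR-26b-5p 2469, miR-29a-3p 2055 and miR-17-5p 2008. Only 6 of the 12 vesicle-sorted names were in the table, against 9 of 9 cell-retained ones, and both lists draw partly on human cells, so the shares are not like for like. By median percentile among detected miRNAs, 25 of the 29 lists stood above 95% of random lists of their size, the exceptions being the Sfmbt2, muscle, stem cell and endothelial lists. The random lists were drawn from all 1915 miRNAs, most of which had no count, so this placement describes presence rather than preference.

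**Figure D2:**
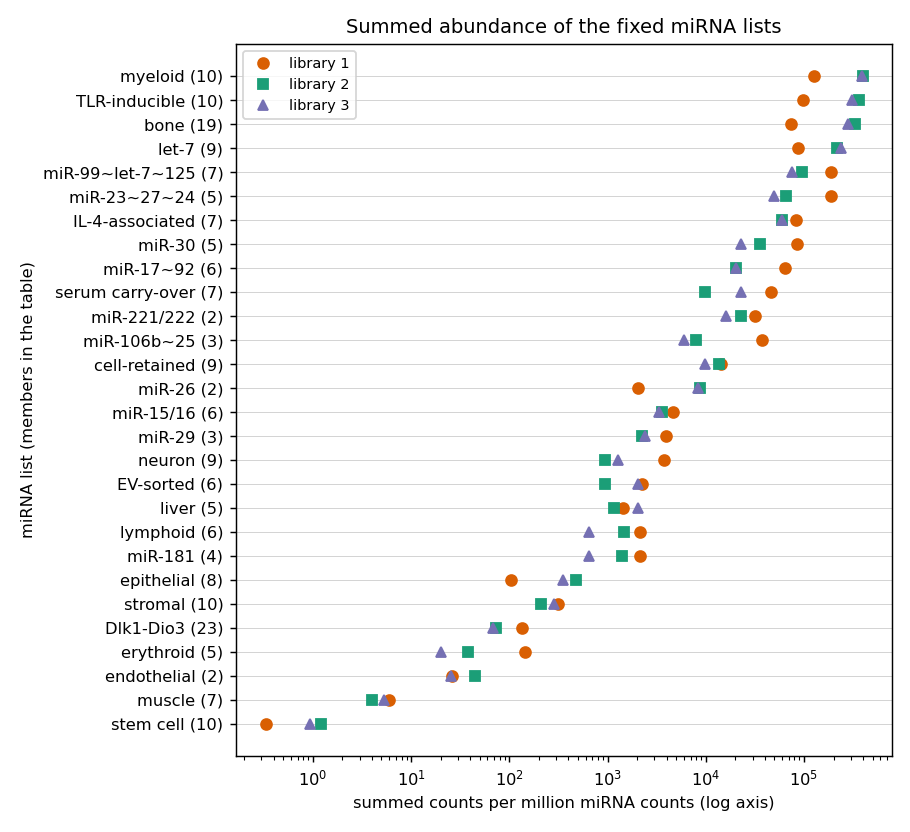
Summed counts per 1000000 miRNA counts (CPM, log axis) of each fixed list in libraries 1 to 3, with the number of members in the table in parentheses. The Sfmbt2 list, with no counts, is not drawn. The myeloid list took 12.5%, 39.5% and 39.0% of counts, and the stem cell list less than 2 CPM in each library.

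How far the 3 exosome libraries resembled each other was compared miRNA by miRNA. Libraries 2 and 3 were close, with a Pearson r of 0.97 and a Spearman rho of 0.94 over 472 miRNAs on the log2(CPM + 1) scale. Library 1 stood apart, with r of 0.91 and 0.89 and rho of 0.85 and 0.82 against libraries 2 and 3. These correlations are across miRNAs, which are not independent replicates. Among the 134 miRNAs with a mean of at least 100 CPM, 75 differed by more than 2-fold between libraries 1 and 2, 92 between libraries 1 and 3, and 35 between libraries 2 and 3. A gap above 4-fold was seen for 44, 51 and 1 of them. The ratios were not centred on 0. Their median on the log2 scale was 0.62 for library 1 over 2, 0.96 for library 1 over 3 and 0.16 for library 2 over 3. Of the 75, 48 were higher in library 1 and 27 in library 2, and of the 92, 63 were higher in library 1 and 29 in library 3. These counts and the chi-square calls thus depend in part on scaling to library totals. The chi-square test found 318 of 353 miRNAs (90.1%) to differ between libraries beyond counting noise at an adjusted p below 0.05. Without library 1 that count was 177, where fewer than 353 miRNAs reached the summed count of 30 and were tested. The coefficient of variation between libraries estimated by edgeR was 76.2%, and 42.9% without library 1.

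The most variable abundant miRNAs were let-7e-5p, at 14.3, 826 and 907 CPM in libraries 1, 2 and 3, miR-5099 at 257, 9725 and 19351 CPM, miR-2137 at 1798, 56.2 and 29.3 CPM, miR-142a-3p at 42.9, 1364 and 819 CPM, and miR-1957a at 329, 12.9 and 15.6 CPM. The steadiest were miR-1843a-5p at 204, 219 and 218 CPM, which did not pass the chi-square test, miR-146a-5p at 33401, 35012 and 36543 CPM, and miR-99b-5p at 4616, 5065 and 5352 CPM. This holds for scaling to library totals, since with TMM factors their log2 ratios of library 1 to library 3 were -0.96, -0.99 and -1.08. Among 98 miRNAs with a mean of at least 300 CPM, the log2 ratio of library 1 to library 2 rose with the GC content of the mature sequence (Spearman rho 0.59, Pearson r 0.58, permutation p = 1e-05, adjusted 1.5e-05), as did that of library 1 to library 3 (rho 0.49, r 0.47, permutation p = 1e-05, adjusted 1.5e-05). Both permutation p-values are the smallest that the permutations can give. For libraries 2 and 3 rho was -0.14 and r was -0.15 (permutation p = 0.161, adjusted 0.161). Of the 40 miRNAs with a GC content of 50% or more, 33 were higher in library 1 than in both other libraries, against 17 of the 40 from 40% to below 50% and 5 of the 18 below 40%. With TMM factors these counts were 24, 15 and 2.

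**Figure D3:**
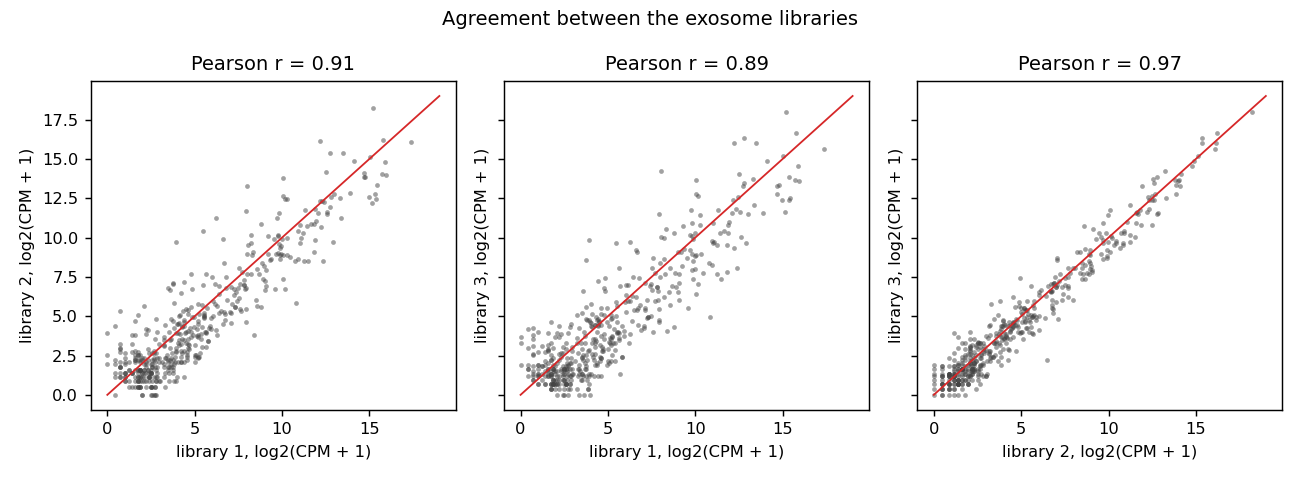
Each point is 1 of 472 miRNAs with a mean of at least 1 CPM, on log2(CPM + 1) axes for each pair of exosome libraries, with the line of equality in red. Points scatter more widely for the pairs with library 1 (r of 0.91 and 0.89) than for libraries 2 and 3 (r of 0.97).

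A miRNA hairpin has a 5p and a 3p arm, of which usually 1 is kept as the mature miRNA. Of 157 hairpins with both arms listed under matching names and enough counts, 126 had unequal arms in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. Of these, 65 favoured the 5p arm and 61 the 3p arm. Some abundant hairpins, such as miR-24, let-7a and let-7c, were not tested because the names of their arms did not match. The hairpins of miR-486a and miR-486b, and of miR-199a and miR-199b, share the reads of their main arm, and with each pair counted once 124 of 155 hairpins passed. Over all 157 hairpins, 138 (87.9%) favoured the same arm in all 3 libraries, and the median share of the minor arm was 1.27%. An arm drawn at random in each library would give 25%, which is a low bar because usually 1 arm of a hairpin is kept. MiR-21a gave 1711437 counts from its 5p arm and 252 from its 3p arm (log2 ratio 12.52, SE 1.02, adjusted p = 8.34e-27 by edgeR). MiR-99a gave 850880 and 23 counts (log2 ratio 15.04, SE 1.15, adjusted p = 2.34e-29 by edgeR), and miR-146a gave 304934 and 7, a ratio of 43562 with a 95% counting interval of 21142 to 108350.

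Other hairpins had no count on 1 arm. MiR-320 gave 14543 counts from its 3p arm and none from its 5p arm, so the 3p arm was at least 680-fold higher in every library against a floor of 3 counts per library. The corresponding bounds for the 3p arm were 846-fold for miR-101b and 67.7-fold for miR-107 and for miR-542. For the 5p arm they were 399-fold for miR-192 and 323-fold for miR-122. MiR-101a gave 16425 counts from its 3p arm and 3 from its 5p arm, a ratio of 5475 (95% counting interval 1873 to 26552).

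Of the 31 hairpins that did not pass, 18 had more counts on the 5p arm in some libraries and on the 3p arm in others, 1 had a tie in a library, and 12 favoured the same arm in all 3 libraries. The examples that follow were chosen after their values were seen, as those with the most counts. The miR-423 hairpin gave 1890 counts from the 5p arm and 23103 from the 3p arm in library 1, 955 and 2052 in library 2, and 5353 and 2575 in library 3. The let-7d hairpin gave 726 and 5855 counts in library 1, 8335 and 1006 in library 2, and 9338 and 963 in library 3. The miR-142a hairpin gave 879 and 129 counts in library 1, 2038 and 3396 in library 2, and 1250 and 2628 in library 3. On simulated counts the test recovered 75% of 16-fold, 10% of 4-fold and 0% of 2-fold arm differences, so many imbalances of 4-fold or less would be missed with 3 libraries this variable.

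**Figure D4:**
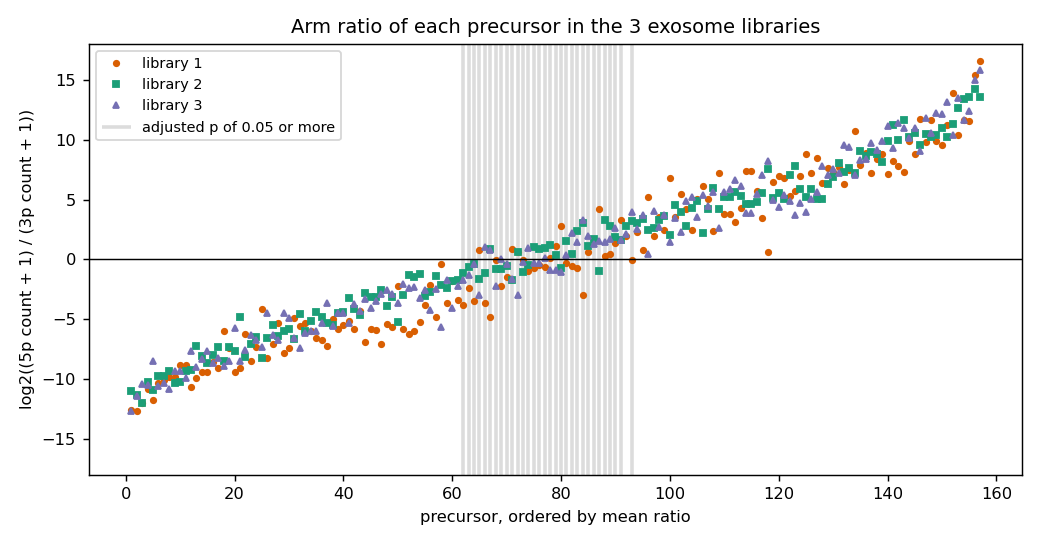
Log2 ratio of 5p to 3p counts, each with 1 count added, for the 157 hairpins ordered by their mean ratio, in libraries 1 to 3. Grey bands mark the 31 hairpins with an adjusted p of 0.05 or more, of which 18 have points on both sides of 0.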

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

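The alternatives of the authors' RPM, the added 2-fold requirement, the thinning for replicate agreement and the TMM counts by GC content were chosen after seeing the data, and the others before. The number of miRNAs with at least 10 counts in every library, 273, became 171 at a minimum of 50 counts, since fewer miRNAs reach it, and lay between 256 and 341 otherwise. The lowest Pearson r between libraries, 0.894, ranged from 0.896 to 0.973 when each library was left out in turn, the highest value without library 1. It was 0.945 with no filter, which adds miRNAs at 0 in all libraries, and 0.699 at a mean of at least 100 CPM, which narrows the range of levels. Of miRNAs differing beyond counting noise, 318 with all libraries, between 177 and 284 were called when each library was left out, the lowest without library 1. At a summed count of at least 300, 168 were called. In each of these settings fewer miRNAs were tested. Of the 318, 270 also differed by more than 2-fold with counts scaled to library totals. The arm test called between 99 and 122 precursors with 1 library left out, 126 with no replicate block, 129 with DESeq2, 130 with limma, 168 with no filter and 89 at a summed count of at least 600, against 126. The top 10 held between 63.7% and 72.8% of counts, 24 to 26 lists stood above 95% of random lists, and 16 to 20 of the top 20 names were shared. The 435 leave-one-out and rescaled values of 87 named miRNAs and the 80 of the 10 named precursors kept within the spread or on their side of the threshold. A mean of 3 libraries cannot move by 1 SD when 1 is left out, so this says little of stability. Of 145 list percentiles 89 moved by less than the spread. No paired analysis was possible because there was 1 group. An alternative planned for tables holding normalized values alone was not run, since counts were deposited. Depth limits the scarce miRNAs, and below about 1 CPM no difference between libraries can be read.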

Other observations

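All tests in this part were chosen after the results they bear on were seen. A single base could separate miRNAs whose ratio differed widely between libraries. Positions count from 1 at the 5′ end of the mature miRNA, and each substitution gives the base of the miRNA named before the other, the position, and the base of the other. MiR-23a-3p was 62.8 times as abundant as miR-23b-3p (T19A) in library 1, and 4.41 and 6.01 times in libraries 2 and 3. The ratio of miR-146a-5p to miR-146b-5p (G18A T21C) was 4.81 in library 1, 0.837 in library 2 and 0.447 in library 3. The ratio of let-7a-5p to let-7c-5p (A19G) was 0.181, 0.773 and 0.772. That of let-7a-5p to let-7f-5p (G12A) was 0.225, 0.195 and 0.195, so not every such pair moved. Over 38 pairs of mature miRNAs with up to 3 mismatches, the ratio differed by more than 4-fold between libraries 1 and 2 for 16, between libraries 1 and 3 for 19 and between libraries 2 and 3 for 0. These are not separate instances, since 12 of the 16 and 15 of the 19 pairs combine the same 9 members of the let-7 family, and 4 of the 13 pairs outside it passed in each case.

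Base composition is a candidate explanation for part of the distance of library 1 from libraries 2 and 3: the lower of the Spearman correlations between GC content and the log2 ratio of library 1 to the other libraries was 0.487, and in 35 miRNAs with a mean of 100 to 300 CPM, by the GC content of the precursor on the side of the arm, rho was 0.43 and 0.38. GC content was argued against as the whole cause, because removing its straight line left an SD of the log2 ratio of library 1 to library 2 of 1.69 (bootstrap 95% interval 1.40 to 1.95), above the 0.815 (0.697 to 0.918) of libraries 2 and 3. Transcription of the miRNA loci as the whole cause was also argued against, because miRNAs of 1 cluster or hairpin, taken to share a primary transcript, differed by a median gap of 1.85 on the log2 scale in that ratio, against 0.97 for libraries 2 and 3 over 22 clusters (permutation p = 0.00252), while randomly regrouped miRNAs gave 2.04 and 0.97, so members of a cluster were not shown to move together in either ratio. RNA of marrow stromal cells could not be judged. The stromal list gained 0.104% of what miR-99a-5p gained from library 2 to library 1, but no profile of stromal cells was available to set the gain expected. Its highest member miR-199a-3p was at 223 and 125.3 CPM in libraries 1 and 2. Sequence-dependent recovery during ligation or PCR, a difference in trimming or in the assignment of reads to near-identical miRNAs, and sequence-dependent turnover or sorting in the cells, stay open, and the labels name no biological difference between the libraries that could be tested.

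MiR-122-5p, a hepatocyte miRNA, and miR-451a, an erythrocyte miRNA, may point to serum left in the culture medium. A carry-over of 1 serum, with its miRNAs recovered alike in all libraries, would keep them in 1 ratio, but the log2 ratio of miR-451a to miR-122-5p was -3.25, -4.99 and -7.06 in libraries 1, 2 and 3, a range of 3.82 (counting SE 0.284). That argues against 1 serum, recovered alike, as the source of both miRNAs. It does not bear on serum as the source of miR-122-5p alone, since miR-451a could then come from elsewhere. Different sera, a serum with unequal recovery between libraries, and expression by cells of the culture stay open. The liver list moved apart as well, with miR-122-5p lowest and miR-192-5p highest in library 1.

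For the 126 hairpins with unequal arms, the 6 columns of arm counts allow 10 splits into 3 and 3, too few for a share under 0.05. Only 1 split, the real one, gave as many calls, 126, and the highest of the other splits gave 0.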
